A study of Arabidopsis thaliana with 6 samples.

How the data were processed

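Small RNA libraries of Arabidopsis thaliana Col-0 were compared in 4 groups: polysome (n = 2), monosome (n = 2), TRAP (n = 1, plants overexpressing His6-Flag-RPL18) and seedling (n = 1). The first 3 groups came from inflorescences. Per the labels, RNA was extracted by phenol/chloroform, and libraries were sequenced on an Illumina HiSeq. The submitters' processing notes name CASAVA 1.8.2 and the TAIR10 genome; the aligner is not given in the sources used here.

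For each library the authors deposited a list of distinct sequences with their counts, meaning the number of times each sequence was seen, with no normalization. The values are whole numbers from 1, and the lists total 5168696 (TRAP) to 25775337 (seedling) counts over lengths of 15 to 44 nt. The lists were checked against the genome. Sequences are written along the plus strand of the genome, and a sequence that matches both strands is listed in both orientations, in most cases with equal counts. Such pairs hold 17.7% (TRAP) to 40.7% (monosome replicate 2) of the reads. Each pair was counted once, with the larger count. The strand of a read is thereby lost, so the first nucleotide was taken as the mean over both orientations, and features were counted without regard to strand.

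Some pairs of at least 100 reads had counts more than 30-fold apart: 5.32% in polysome replicate 1, 5.16% in polysome replicate 2, 2.26% in monosome replicate 1, 0.654% in monosome replicate 2, 0 of 319 in the TRAP library, which allows up to 1.19% (Wilson 95% limit), and 21.9% in the seedling library. The larger count was kept for pairs, but a sequence listed once cannot be corrected. A low sequence was therefore defined as one more than 30-fold below the other inflorescence libraries, where it had at least 10 CPM. There were 56 in polysome replicate 1, 68 in polysome replicate 2, 6 in monosome replicate 1, 63 in monosome replicate 2 and 77 in the TRAP library. Among the listed miRNAs this held for miR161.1, with 3 reads in polysome replicate 1 and 14435 in polysome replicate 2.

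Sequences of 18 to 30 nt were matched exactly to the TAIR10 nuclear and organelle genomes (Python 3.11.15, numpy 2.4.6, numba 0.67.0, pandas 2.3.3). A read that matched several places was divided evenly among them, and its middle base decided the gene. Where genes overlapped, organelle, miRNA, TAS, rRNA, tRNA, snoRNA and snRNA genes took precedence, in that order, over pseudogenes, transposable element genes, protein-coding genes and other non-coding RNA genes. The 25S rRNA, which the annotation lacks, was taken as 4000 bp after each 5.8S gene, and 5S copies were found with blastn 2.17.0 (at least 100 bp and 90% identity). The annotation does not mark transposable element genes, so genes of biotype pseudogene without a pseudogene note were assumed to be transposable element genes. Mature miRNAs were counted as exact sequences from a list of 52, of which 50 had reads; miR169b-5p and miR828 were not analysed here. Shares of reads were computed per library and compared by a two-sided exact permutation test (scipy 1.17.1), which has 6 arrangements and a smallest p of 0.333. Intervals for single libraries are Wilson 95% intervals, and the floor is 3 counts. CPM are reads per 1000000 reads of 18-30 nt.

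Features (mature miRNAs, and reads of 20-22 nt and of 23-25 nt of each gene) were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM factors (1.19 and 1.27 for polysomes, 0.789 and 0.834 for monosomes), robust quasi-likelihood F-tests and a Benjamini-Hochberg threshold of 0.05. Read counts divided among places are fractions, and they were rounded for DESeq2 1.42.0. The common dispersion was 0.098. Spearman correlations across features, which are not independent replicates, were 0.858 between the polysome replicates, 0.756 between the monosome replicates and 0.715 to 0.790 between fractions. The pipeline was tested on simulated data with the means, library sizes and dispersions of the polysome and monosome libraries. The changed features were drawn only from those with a mean of at least 5 CPM, so recovery of rarer features was not tested. At a log2 change of 2, 69 of 100 changed features were recovered, and at a log2 change of 3, 97 of 100, with 15 false calls among 7645 features tested. The simulated counts were independent, without divided reads or lost counts, so recovery in the libraries can be lower. In the libraries AT1G76550, at a log2 fold change of 3.40, was not called by this fit (FDR = 0.285). Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 and with an estimated one. The lists were conserved miRNAs (38 listed), Brassicaceae miRNAs (14), miRNAs of 22 nt, TAS loci (8), target genes of miRNAs and trans-acting siRNAs (54), PPR genes (14), NB-LRR genes (12), pseudogenes, transposable element genes, and tRNA, rRNA, snoRNA and snRNA and organelle genes. Gene lists were split by read size, and the result of each tested list is given in the results.

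The genes to name were fixed by a rule. It took every TAS locus. Of listed miRNAs with at least 20 CPM it took the 8 largest changes per direction that pass, or, where fewer than 4 passed, the 4 largest. Of pseudogene, transposable element gene and protein-coding features with at least 5 CPM it took the 4 largest changes per direction that pass, or, where none passed, the 2 with the lowest p. It also took the 5 most abundant pseudogene features in polysomes. For the TRAP library beside the polysome mean, and the seedling library beside the mean of the 5 inflorescence libraries, it took the 5 miRNAs of at least 100 CPM at each end and the 3 pseudogenes and 3 transposable element genes with most reads. Alternatives covered scaling (DESeq2 size factors, no TMM, TMM without structural and organelle features), the test (DESeq2), the low-count filter, the treatment of reads with several places, a replicate block, all libraries in one fit, each replicate left out, distinct sequences, other denominators and all reads of a MIR gene. Counting both orientations as listed, leaving out the low sequences, scaling without TMM for the lists, a denominator without miRNA reads, leaving out AT3G43832 for pseudogene shares, and all reads of a MIR gene for single libraries were added after the data were seen. Reads outside 18-30 nt were left out of the comparisons. Figures were drawn with matplotlib 3.10.9.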

Results

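Small RNA reads of Arabidopsis thaliana Col-0 were compared between RNA that sedimented with polysomes, messages carrying several ribosomes, and RNA that sedimented with monosomes, single ribosomes. The data comprised 6 libraries. The inflorescence libraries were 2 polysome, 2 monosome and 1 TRAP library, in which ribosomes were purified by affinity from plants overexpressing a tagged ribosomal protein, His6-Flag-RPL18. The sixth library held small RNA of seedlings without a ribosome step. Reads of 18-30 nt numbered 8490068 and 9461364 in the polysome libraries, 3381062 and 3118492 in the monosome libraries, 3425788 in the TRAP library and 17108870 in the seedling library. Between 87.8% (TRAP) and 93.5% (polysome replicate 2) of these reads matched the TAIR10 genome exactly. Confidence intervals and floors given here cover counting error only, since the reads carry no molecular identifiers. The p-values measure only the spread between these libraries, as nothing in the labels states that the replicates came from separate plants. Lists, tests, named-gene rule and most alternatives were chosen before the data were examined.

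The series asks which small RNAs associate with polysomes, with the 24-nt class named in its title. In Arabidopsis most miRNAs are 21 nt long and most siRNAs of the RNA-directed DNA methylation pathway are 24 nt long. The 24-nt class took a larger share of the reads in both polysome libraries than in either monosome library. It made up 29.8% ± 3.30 (SD, n = 2) of polysome reads and 18.7% ± 0.495 (SD, n = 2) of monosome reads, a difference of 11 percentage points. The 21-nt class held similar shares, 32.4% ± 7.91 in polysomes and 32.3% ± 2.78 in monosomes, with the polysome libraries on both sides of the monosome ones. The 22-nt class was at 7.02% ± 0.497 in polysomes and 7.58% ± 0.633 in monosomes, and these ranges overlapped. The 23-nt class, whose share was looked at after its values were seen, went the other way from the 24-nt class, with 5.03% ± 0.419 in polysomes and 7.22% ± 0.154 in monosomes. The log2 ratio of 24-nt to 21-nt reads was higher by 0.68 in polysomes, with values of 0.26 and -0.47 against -0.67 and -0.90. This difference was 0.31 without polysome replicate 1 and 1.04 without polysome replicate 2. The difference in the 24-nt share exceeded the spread between replicates, but the two-sided exact permutation test of 2 libraries against 2 cannot give a p below 0.333, the value it gave for the 24-nt share and for the log2 ratio. Counted as distinct sequences the 24-nt difference was 2.37 percentage points, and the log2 ratios of the groups then overlapped.

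**Figure D1:**
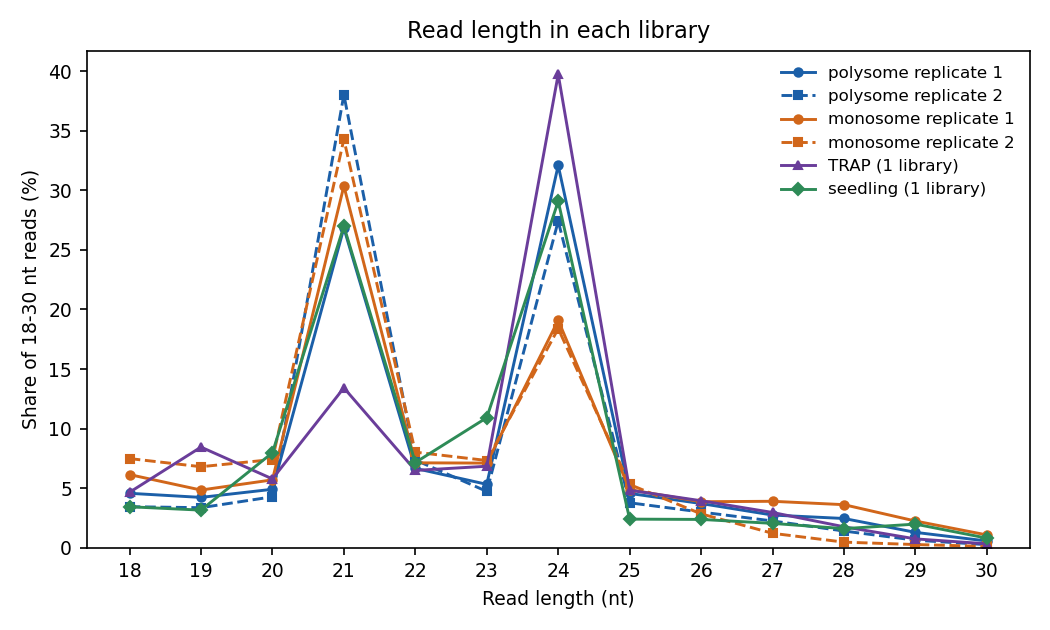
Share of 18-30 nt reads (percent) at each read length (nt) in the 6 libraries, with one line per library. At 24 nt the polysome libraries stand at 32.1% and 27.4%, the monosome libraries at 19.1% and 18.4%, and the TRAP library at 39.7%.

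Reads of pseudogenes, transposable element genes, protein-coding genes and intergenic regions held larger shares of the polysome libraries, as did tRNA, snoRNA and snRNA fragments, when reads that match several places were included. Ribosomal and organelle RNA fragments held larger shares of the monosome libraries. Pseudogenes, the second group named in the title of the series, gave 1.51% ± 0.217 (SD, n = 2) of genome-matched polysome reads and 0.659% ± 0.108 of monosome reads. A single pseudogene, AT3G43832, supplied much of this, and without it the shares were 0.744% ± 0.108 and 0.436% ± 0.0361. Transposable element genes gave 3.43% ± 0.00650 and 2.07% ± 0.0312, and protein-coding genes 8.17% ± 0.337 and 4.32% ± 0.105. Intergenic reads were at 22.3% ± 2.48 and 14.2% ± 0.615. Within the 24-nt reads alone, pseudogenes held 3.96% ± 0.162 in polysomes and 2.39% ± 0.392 in monosomes, but 1.66% ± 0.121 and 1.41% ± 0.0830 without AT3G43832. Reads of miRNA genes did not separate the fractions, at 30.5% ± 9.12 and 27.9% ± 3.0, nor did TAS loci, the sources of trans-acting siRNAs, at 0.211% ± 0.0499 and 0.212% ± 0.00996. Fragments of tRNA were at 1.33% ± 0.140 in polysomes and 0.701% ± 0.148 in monosomes, and snoRNA and snRNA fragments at 0.522% ± 0.0872 and 0.309% ± 0.0324. Fragments of rRNA were at 19.3% ± 3.20 in polysomes and 32% ± 6.25 in monosomes, and organelle reads at 10.4% ± 2.48 and 16.5% ± 4.27. The rRNA difference of -12.8 percentage points was -8.34 without monosome replicate 1 and -17.2 without monosome replicate 2, and the organelle difference of -6.12 was -9.14 and -3.10. These rRNA and organelle shares moved with the fraction beside the pseudogene, transposable element gene, protein-coding and intergenic shares, and reads of 15-17 nt, outside the lengths compared, did so too, with 15.8% and 14.3% of the polysome counts and 25.5% and 29.3% of the monosome counts. With reads that match a single place, transposable element genes no longer separated the fractions (5.31% ± 0.389 and 5.21% ± 0.129), nor did snoRNA and snRNA fragments (1.08% ± 0.254 and 0.993% ± 0.113). The differences were then -2.15 percentage points for rRNA, -2.82 for organelle reads, 0.143 for tRNA and 4.45 for intergenic reads. With all reads they were 0.634 for tRNA and 8.17 for intergenic reads. The sizes of the 2 sets of differences cannot be compared, because the former are shares of single-place reads only. Among those, rRNA was at 1.851% ± 0.180 in polysomes and 3.997% ± 0.470 in monosomes, and tRNA at 0.321% ± 0.152 and 0.178% ± 0.0472. Reads of miRNA genes (-4.77) and TAS loci (-0.335) were then lower in both polysome libraries. For each class called separate here the exact permutation p was 0.333, the smallest that 2 libraries against 2 can give. Shares of a whole depend on each other, so a class can be higher because rRNA and organelle reads are lower.

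**Figure D2:**
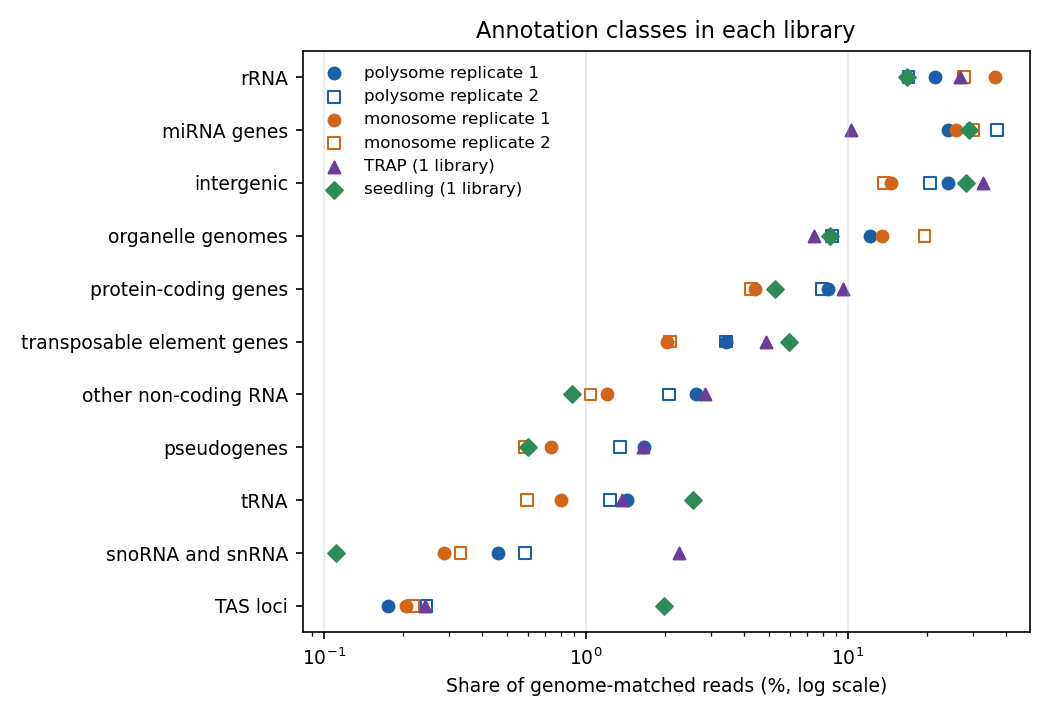
Share of genome-matched reads (percent, log scale) in each annotation class, with one symbol per library. Pseudogene shares are 1.66% and 1.35% in the polysome libraries and 0.735% and 0.583% in the monosome libraries, while rRNA shares are 21.5% and 17% against 36.4% and 27.6%.

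The most abundant pseudogene was AT3G43832 (TAIR10 chromosome 3, 15682293 to 15682874). Its 23-25 nt reads reached 7506 and 6194 reads per 1000000 reads (CPM) in the polysome libraries and 2337 and 1434 in the monosome libraries. The edgeR log2 fold change was 1.25 (SE 0.46, FDR = 0.423), which did not pass the test. One 24-nt sequence, AATTCATACGACATGACCCTCCAT at 15682298 to 15682321, made up 60.0% of the polysome reads of 23-25 nt that match only this locus. It had 35669 and 37237 reads in the polysome libraries, 3770 and 2124 in the monosome libraries, 9132 in the TRAP library and 5 in the seedling library. The 23-25 nt reads of AT2G45090, AT1G47880 and AT3G23645 were next, with polysome means of 794 ± 226, 528 ± 236 and 429 ± 221 CPM (SD, n = 2) and monosome means of 324 ± 31.3, 234 ± 89.2 and 155 ± 52.5 CPM. Their log2 fold changes were 0.70, 0.57 and 0.87, and without polysome replicate 1 these were 0.28, -0.08 and 0.11. With another library left out AT3G23645 was at 1.34 (polysome replicate 2), 1.36 (monosome replicate 1) and 0.55 (monosome replicate 2). The 20-22 nt reads of AT4G21370, the pseudogene of the self-incompatibility receptor kinase SRK, were at 439 ± 40.2 and 328 ± 32.3 CPM, with a log2 fold change of -0.18 that was 0.42 without TMM scaling. None of these 5 pseudogenes passed the test in edgeR or DESeq2. As lists, pseudogene features were balanced after TMM scaling: of those with 23-25 nt reads 88 were higher and 100 lower (median -0.02, camera adjusted p = 0.586), and of those with 20-22 nt reads 33 were higher and 35 lower (median -0.01, adjusted p = 0.596). Without TMM scaling 158 were higher and 30 lower at 23-25 nt (median 0.58, camera adjusted p = 0.921). At 20-22 nt 54 were then higher and 14 lower (median 0.60, camera adjusted p = 0.674). The 2 pseudogene features with the lowest p did not pass in edgeR with all 4 libraries and the low-count filter. Both were of AT2G07688 on chromosome 2 and lower in polysomes, by log2 fold changes of -1.81 (SE 0.34, FDR = 0.285) and -1.66 (SE 0.37, FDR = 0.292). DESeq2 called its 20-22 nt reads (-1.82), as did edgeR without the low-count filter (-1.58), without polysome replicate 1 (-2.04), without monosome replicate 1 (-1.74) and without monosome replicate 2 (-1.83), and edgeR called its 23-25 nt reads without monosome replicate 1 (-1.82). Its reads also match other places, and it had too few reads that match a single place to be tested with those alone.

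Among all small RNA features no change passed the threshold in the edgeR fit fixed beforehand. This fit had all 4 libraries, the low-count filter, divided reads and no replicate block. A feature was an exact mature miRNA or the 20-22 nt or 23-25 nt reads of an annotated gene. Of 8027 features tested, 4002 were higher in polysomes and 4025 lower, 864 had an unadjusted p under 0.05 (463 higher, 401 lower), and the lowest FDR was 0.184. DESeq2 called 83 features, 33 higher and 50 lower in polysomes. Those higher included 19 tRNA, 6 protein-coding and 5 organelle features, and those lower included 33 organelle, 6 rRNA and 4 snoRNA or snRNA features. The lowest p in edgeR belonged to the 23-25 nt reads of the snoRNA gene AT1G09877, named after its values were seen, with 23.6 and 30.3 CPM in polysomes and 214 and 263 CPM in monosomes (log2 fold change -3.75, SE 0.37, FDR = 0.184). With all 4 libraries edgeR called it at a mean of at least 10 CPM, with reads that match a single place and with each place counting the full read, where 5, 3 and 1 features were called, all lower in polysomes. The others in these settings were the snoRNA or snRNA gene AT4G08125, named after its values were seen, and 3 organelle genes. Without the low-count filter edgeR called 183 features. The protein-coding features with the lowest p were 23-25 nt reads of AT1G76550, a phosphofructokinase family gene, and of GCN2 (AT3G59410), the kinase that phosphorylates the translation initiation factor eIF2 alpha. AT1G76550 had 15.1 ± 3.18 CPM in polysomes and 0.937 ± 0.489 in monosomes, where it had only 2 and 4 reads (log2 fold change 3.40, SE 0.50, FDR = 0.285). GCN2 had 27.3 ± 6.65 and 2.76 ± 0.275 CPM, with 10 and 8 monosome reads (log2 fold change 2.70, SE 0.43, FDR = 0.285). DESeq2 called both, and so did edgeR without the low-count filter (3.62 and 2.94) and with any 1 library left out, at 3.0 to 4.0 for AT1G76550 and 2.33 to 2.95 for GCN2. The transposable element genes AT2G11240 and AT3G44035 had log2 fold changes of 1.86 (SE 0.41) and 1.78 (SE 0.41), both at FDR above 0.05 in edgeR and DESeq2. In edgeR both were called without the low-count filter (2.08 and 2.02), AT2G11240 without polysome replicate 1 (2.05), and AT3G44035 without polysome replicate 2 (2.00) and without monosome replicate 2 (2.14). AT2G11240 had too few reads that match a single place to be tested with those alone. TMM scaling, which makes the bulk of features even, removes a median log2 shift of 0.60, and without it 83.0% of the features were higher in polysomes in place of 49.9%. The count of 0 rested on the 4 libraries together, as features were called with any 1 library left out. The lone library of a fraction is then assumed to vary like the other fraction. Most features called without polysome replicate 1 were copies of the 5S rRNA gene. Such copies share divided reads, so they do not count separate small RNAs.

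Of 43 listed miRNAs tested, 23 were higher and 20 lower in polysomes after TMM scaling, and 35 were higher and 8 lower without it. None passed the threshold in edgeR or DESeq2, over all features or adjusted over the list alone (lowest adjusted p in edgeR 0.120). Of the 43, 6 had an unadjusted p under 0.05 in edgeR and 4 in DESeq2. Chosen after its values were seen, miR393a-5p, which targets auxin receptor transcripts, had the lowest p, with a log2 fold change of -1.71 (SE 0.37) at few reads (2.83 and 2.43 CPM in polysomes, 5.62 and 5.77 in monosomes). Among miRNAs with at least 20 CPM, the largest differences upward were those of miR163, a Brassicaceae miRNA that targets methyltransferase transcripts, at 556 ± 69.4 CPM in polysomes and 176 ± 18.7 in monosomes (log2 fold change 1.05, SE 0.36), miR156a-5p, which targets SPL transcripts (0.66, SE 0.43), miR319a, which targets TCP transcripts (0.64, SE 0.55) and miR171a-3p (0.40, SE 0.32). The largest differences downward were those of miR159a, which targets MYB transcripts (-1.29, SE 0.47), miR396b-5p, which targets GRF transcripts (-0.70, SE 0.38), miR158a-3p (-0.56, SE 0.43) and miR166a-3p, which targets HD-ZIP III transcripts (-0.49, SE 0.45). None of these 8 passed the test. The miR166a-3p sequence alone reached 192844 ± 56372 CPM in polysomes and 177253 ± 12102 CPM in monosomes and is shared by 7 places of the genome. Without TMM scaling miR158a-3p and miR166a-3p were at 0.05 and 0.12, and with all reads of the gene counted miR171a-3p was at -0.27. Such counts add the other 20-22 nt reads of the gene to the mature sequence, without other listed mature sequences. The value of miR319a was 0.05 without polysome replicate 2, 0.24 without monosome replicate 1, 1.02 without polysome replicate 1 and 1.23 without monosome replicate 2. Some miRNAs were called when a library was left out, all named after their values were seen. Without polysome replicate 2 miR161.1 was at -10.7, which rests on its 3 reads in polysome replicate 1 (replicate 2 had 14435). Together with the other 20-22 nt reads of its gene, but without miR161.2, it came to 426 CPM in polysome replicate 1. miR395b, with 0 and 9 monosome reads, was at 2.71 without polysome replicate 1 and 8.85 without monosome replicate 2. miR825, with 0 and 18 monosome reads, was at -2.89 without monosome replicate 1. Without monosome replicate 2 miR393a-5p was at -1.72 and miR822-5p, with 1 and 4 monosome reads, at 3.58. By class, 15 conserved miRNAs were higher and 16 lower (camera adjusted p = 0.480), 8 Brassicaceae miRNAs were higher and 4 lower (adjusted p = 0.951), and 1 miRNA of 22 nt was higher and 3 lower (adjusted p = 0.10).

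**Figure D3:**
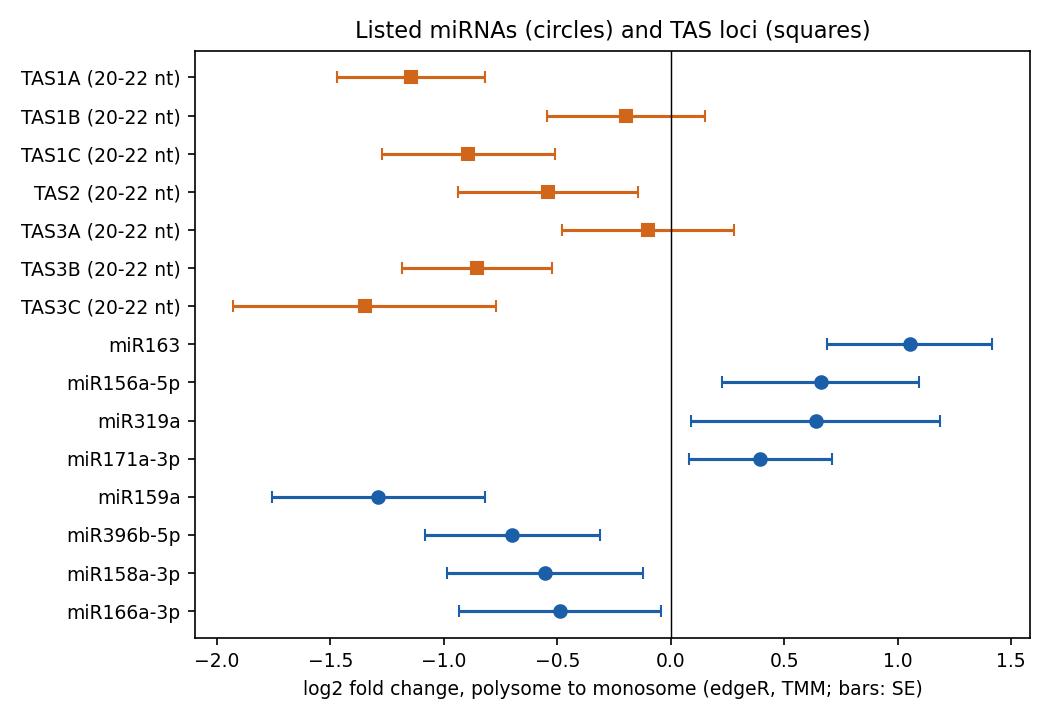
log2 fold change between polysome and monosome libraries (edgeR with TMM scaling, 2 libraries per group) with its SE as bars, for the 8 named miRNAs and the 7 TAS loci with enough 20-22 nt reads. No feature shown passed this test with all 4 libraries, and TAS1B, TAS2, TAS3A, miR158a-3p and miR166a-3p changed sign without TMM scaling.

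The TAS loci, which produce trans-acting siRNAs after cleavage by miR173, miR390 or miR828, were lower in polysomes relative to the bulk of features in a list test that passed only with a preset correlation. After TMM scaling all 7 tested TAS loci had lower 20-22 nt reads in polysomes (median log2 fold change -0.85) and all 6 tested had lower 23-25 nt reads (median -1.0). With the preset correlation camera gave adjusted p = 0.00161 and 2.74e-04 for these lists. Neither call held with an estimated correlation, at adjusted p = 0.681 and 0.375, and that of the 20-22 nt reads was lost without polysome replicate 1 (adjusted p = 0.0818) and without monosome replicate 1 (adjusted p = 0.133). By itself no TAS locus passed in edgeR with all 4 libraries, while DESeq2 called the 23-25 nt reads of TAS1C (log2 fold change -1.39, FDR = 0.0381). For 20-22 nt reads the log2 fold changes were -1.15 (SE 0.33) for TAS1A, -0.20 (SE 0.35) for TAS1B, -0.89 (SE 0.38) for TAS1C, -0.54 (SE 0.40) for TAS2, -0.10 (SE 0.38) for TAS3A, -0.85 (SE 0.33) for TAS3B and -1.35 (SE 0.58) for TAS3C. The value of TAS3C was -0.21 without monosome replicate 1 and -1.96 without monosome replicate 2, where it passed in edgeR (FDR = 0.00700). TAS1B turned to 0.07 without monosome replicate 2, and TAS3A to 0.05 both without polysome replicate 1 and without monosome replicate 1. For 23-25 nt reads they were -0.66 for TAS1A, -0.84 for TAS1B, -1.37 for TAS1C, -1.16 for TAS2, -0.43 for TAS3A and -1.54 for TAS3B, with TAS3A at 0.49 without monosome replicate 1 and TAS1A at -0.05 without monosome replicate 2. TAS4 had at most 2 reads of 20-22 nt in any inflorescence library and was not tested. Without TMM scaling the 20-22 nt values of TAS1B, TAS2 and TAS3A were 0.40, 0.07 and 0.51, and the 23-25 nt value of TAS3A was 0.19.

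Structural and organelle RNA fragments gave the other calls among the 21 lists tested with camera, of which 8 had an adjusted p under 0.05 with the preset correlation and none with the estimated one. Fragments of tRNA were higher in polysomes in 115 of 137 features of 20-22 nt (median 0.58, adjusted p = 3.05e-06, with an estimated correlation adjusted p = 0.722) and in 133 of 203 features of 23-25 nt (median 0.32, adjusted p = 0.00161, with an estimated correlation adjusted p = 0.681). After TMM scaling all 8 rRNA features, and without it 6 of 8, were lower at 20-22 nt (median -0.91, adjusted p = 4.32e-06) and at 23-25 nt (median -1.05, adjusted p = 3.05e-06), each with adjusted p = 0.375 under an estimated correlation. The 8 rRNA features are adjoining parts of the same transcribed rRNA units, so they are not 8 independent observations. The snoRNA and snRNA features of 20-22 nt were higher in 90 of 147 (median 0.37, adjusted p = 0.0185, with an estimated correlation adjusted p = 0.871). Organelle genes of 23-25 nt were lower in 124 of 203 after TMM scaling, though in 68 of 203 without it (median -0.24 and 0.35), and camera, which compares a list with the other features, called them lower (adjusted p = 0.00457, with an estimated correlation adjusted p = 0.871). With reads that match a single place, the tRNA calls were lost (adjusted p = 0.439 at 20-22 nt and 0.366 at 23-25 nt), as was that of rRNA at 20-22 nt (adjusted p = 0.0599). The organelle call was lost without polysome replicate 1 (adjusted p = 0.0894) and without monosome replicate 2 (0.666), that of tRNA at 23-25 nt without monosome replicate 1 (0.464), and that of snoRNA and snRNA without polysome replicate 2 (0.240) and without monosome replicate 1 (0.647). The snoRNA and snRNA call was also lost at a mean of at least 10 CPM (adjusted p = 0.559) and without TMM scaling (0.0930).

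The counts that follow hold after TMM scaling, and without it most features of each list were higher in polysomes. These lists did not pass with all 4 libraries and TMM scaling, except organelle genes of 20-22 nt with a stricter filter or with reads that match a single place. Transposable element genes had 1252 features higher and 1032 lower at 23-25 nt (median 0.06, adjusted p = 0.296) and 264 higher and 354 lower at 20-22 nt (median -0.08, adjusted p = 0.217). The first of these lists passed without TMM scaling (median 0.66, adjusted p = 0.00685), and the second, toward lower values, without polysome replicate 2 (adjusted p = 0.0268). PPR genes, which give secondary siRNAs, had 10 of 13 features higher at 20-22 nt (adjusted p = 0.217), and this list passed without polysome replicate 1 (adjusted p = 0.0124) and without monosome replicate 2 (0.0456). Target genes of miRNAs and trans-acting siRNAs had 8 higher and 9 lower at 20-22 nt (median -0.09, mean 0.16, camera direction lower, adjusted p = 0.900) and 3 of 3 higher at 23-25 nt (adjusted p = 0.586). NB-LRR genes, disease resistance genes, had 2 higher and 3 lower at 23-25 nt (adjusted p = 0.765). Organelle genes of 20-22 nt were split, with 95 higher and 97 lower (adjusted p = 0.511), and passed as lower in polysomes with reads that match a single place (adjusted p = 1.29e-06), at a mean of at least 10 CPM (0.00625) and without monosome replicate 1 (0.0243). The snoRNA and snRNA features of 23-25 nt had a median of 0.10 but a camera direction of lower (adjusted p = 0.800), and passed as lower without polysome replicate 2 (adjusted p = 0.0327).

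Argonaute proteins differ in the first nucleotide they bind, so the first nucleotide was compared. The deposited sequences are written along the genome and do not keep the strand of the read, so each value is the mean over the base at the left end and the complement of the base at the right end. These values are not shares of true 5′ nucleotides. For pseudogene reads of 24 nt, A reached 67.5% ± 0.589 (SD, n = 2) in polysomes and 59.8% ± 1.91 in monosomes, while G was at 11.8% ± 1.56 and 15.6% ± 0.859 and U at 10.6% ± 0.660 and 14.1% ± 0.274. Without AT3G43832, A was at 48.1% ± 2.76 and 50.2% ± 0.623, which overlapped, and counted as distinct sequences A was lower in polysomes by -1.64 percentage points. For all 24-nt reads, A was at 48.5% ± 1.60 and 46.2% ± 1.86, which overlapped. For all 21-nt reads, U was at 45.6% ± 1.92 and 42.6% ± 0.974, and with reads that match a single place it was lower in polysomes by -8.17 percentage points. The exact permutation test gives at least 0.333 for each of the 16 comparisons of this kind.

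The TRAP library, of which there was 1, had a 24-nt share of 39.7% (Wilson 95% interval 39.7% to 39.8%), above the other libraries, and a 21-nt share of 13.4% (13.4% to 13.5%), below them. With reads that match a single place, polysome replicate 1 was above it at 24 nt (64.8% against 64.7%) and below it at 21 nt (7.97% against 8.04%). At 24 nt polysome replicate 1 was also above it without structural, organelle and miRNA reads (67.8% against 67.0%), and the seedling library was level with it for distinct sequences (46.6% in both). With 1 library there was no replicate check, no test was made, and its genotype differed from that of the other libraries. Reads of miRNA genes made up 10.3% of its genome-matched reads (10.2% to 10.3%), against 24.0% and 36.9% in the polysome libraries. Pseudogenes made up 1.65% (1.63% to 1.66%), within the polysome range of 1.35% to 1.66%. Fragments of snoRNA and snRNA were at 2.26% (2.24% to 2.28%), against 0.460% and 0.583%. Of 18 miRNAs compared with the polysome mean, 4 were higher and 14 lower, with a median log2 ratio of -0.57. The lowest were miR165a-3p (-2.40), miR166a-3p (-2.22), miR156a-5p (-2.16), miR403-3p (-1.63), which targets AGO2, and miR168a-5p (-1.23), which targets AGO1. At the other end were miR159a (0.57), miR390a-5p (0.43), miR159b-3p (0.36), miR157a-5p (0.05) and miR163 (-0.04). The last 2 changed sign with all reads of the gene counted, to -0.02 and 0.16. The pseudogenes with most reads were again AT3G43832 (5655 CPM against 7106 in the polysome mean), AT2G45090 (990 against 929) and AT1G47880 (933 against 581). The transposable element genes with most reads were AT1G77095 (1334 against 1322 CPM), AT5G40605 (725 against 754) and AT3G43730 (639 against 518).

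The seedling library, also single, stood apart from the inflorescence libraries in its trans-acting siRNAs and in several abundant miRNAs. Tissue and ribosome association cannot be told apart here, as the seedling RNA had no ribosome step, and no test was made with 1 library. Reads of TAS loci made up 1.98% of its genome-matched reads (Wilson 95% interval 1.98% to 1.99%), against 0.176% to 0.247% in the inflorescence libraries. The 20-22 nt reads of TAS1A, TAS1C and TAS2 were 22.6-fold, 14.4-fold and 9.73-fold the mean of the 5 inflorescence libraries, those of TAS1B 4.77-fold and those of TAS3A 3.54-fold, while TAS3B was at 0.935-fold and TAS3C at 1.31-fold. TAS4 was at 99.9 CPM, against 0.641 CPM or less in the inflorescence libraries. Of 20 miRNAs compared, 12 were higher and 8 lower in the seedling library. The highest ratios were those of miR157a-5p (log2 ratio 5.55), miR398b-3p (5.26), which targets copper superoxide dismutase transcripts, miR156a-5p (4.79), whose family is known to be high in young plants, miR158a-3p (3.45) and miR161.2 (2.72), the last at 1.02 with all reads of the gene counted. Lower were miR319a (-2.70), miR163 (-2.12), miR390a-5p (-1.97) and miR168a-5p (-0.67), of which miR163 was at -1.52 and miR168a-5p at 0.40 with all reads of the gene counted. The lowest ratio, that of miR161.1 (-13.27, counting interval -18.58 to -10.80), rested on 1 read, and was -0.27 with all reads of the gene counted. In the seedling list, 21.9% of the sequences listed in both orientations with at least 100 reads had counts more than 30-fold apart. The 24-nt share was 29.1% (29.1% to 29.1%) and the 21-nt share 27.0% (27.0% to 27.0%), while the 23-nt share, at 10.9% (10.9% to 10.9%), was above the 4.74% to 7.33% of the inflorescence libraries. The pseudogenes with most reads were AT5G32690 (318 CPM, against 144 in the inflorescence mean), AT3G26775 (186 against 24.1) and AT3G32990 (140 against 17.1), the last with a log2 ratio of 3.04 that was 1.31 with reads that match a single place. AT5G32690 spans 12332283 to 12390801 on chromosome 5, far longer than the others named with it. By the order of precedence it takes the reads of any transposable element or protein-coding gene inside it. The transposable element genes with most reads were AT3G43730 (388 against 436 CPM), AT1G43740 (238 against 207) and AT1G57900 (220 against 202), and AT1G57900 had a log2 ratio of -3.44 with reads that match a single place. AT1G57900 covers only 27688163 to 27688234 of chromosome 1, so its class, assumed from its biotype, is doubtful. The 5 pseudogenes named for their polysome reads had, in the seedling library, 5.09 CPM of 23-25 nt for AT3G43832, 15.1 for AT2G45090, 1.8 for AT1G47880 and 0.175 for AT3G23645, and 1.71 CPM of 20-22 nt for AT4G21370.

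A set of loci with abundant 23-25 nt reads in inflorescences was nearly empty in the seedling library. This comparison and the loci named for it were chosen after the values were seen. Of 627 loci with at least 10 CPM of 23-25 nt reads in each of the 5 inflorescence libraries, 61 were more than 30-fold below the lowest inflorescence library in the seedling library, with a median log2 ratio of -7.91. These were 35 of 246 protein-coding genes, 16 of 59 other non-coding RNA genes, 7 of 38 pseudogenes, 2 of 280 transposable element genes and 1 of 4 miRNA genes. Some of the 61 adjoin or overlap, such as AT2G16575 and AT2G16580, so this is not a count of independent loci. The pseudogene AT3G43832 led the set, with 4569 ± 2585 CPM (SD, n = 5) in inflorescences and 5.09 CPM in the seedling library. Next were AT4G08545, annotated as a receptor-like protein with leucine-rich repeats (2014 ± 906 against 8.10 CPM), and AT1G49260, annotated as a mechanosensitive ion channel-like protein (1642 ± 909 against 1.81 CPM). PIRL2 (AT3G26500), a gene for a leucine-rich repeat protein, had 989 ± 633 against 3.62 CPM. In the opposite direction, 226 loci, 118 of them transposable element genes, were higher in the seedling library than in each inflorescence library. No test was made with 1 seedling library.

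**Figure D4:**
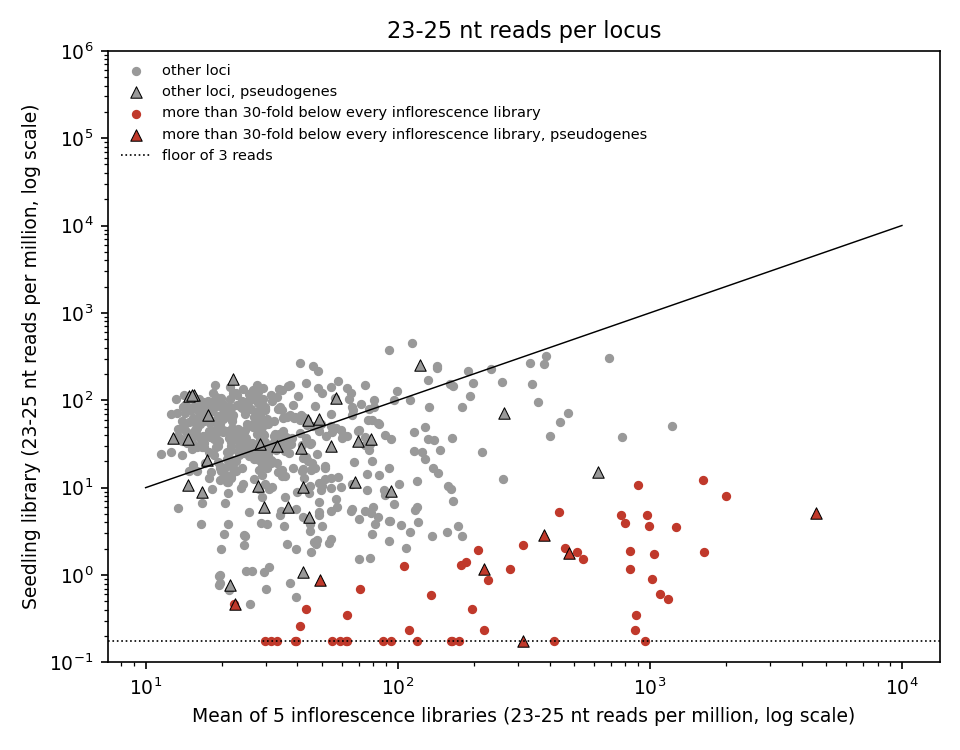
Reads of 23-25 nt in CPM at 627 loci, with the mean of 5 inflorescence libraries on the horizontal axis and the seedling library on the vertical axis (both log scale), where the solid line marks equal values and the dotted line 3 reads. The 61 loci in red are more than 30-fold below each inflorescence library, and triangles mark pseudogenes.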

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

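The values below come from read lengths that the comparisons did not use, and both counts were chosen after the lists were seen. Reads of 15-17 nt made up 15.8% and 14.3% of the listed counts in the polysome libraries, 25.5% and 29.3% in the monosome libraries, 21.7% in the TRAP library and 14.1% in the seedling library.

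Reads of 31-36 nt that begin at the first base of a tRNA gene, called 5′ tRNA fragments here, were present in each library above the limit that 3 counts allow, at 2571 and 88.5 reads per 1000000 reads of 18-30 nt in the polysome libraries, 604 and 180 in the monosome libraries, 178 in the TRAP library and 1412 in the seedling library. The polysome replicates thus differed far more in these fragments than the monosome replicates did. A 33-nt fragment of tRNA-Glu (AT3G50665) had 8439 reads in polysome replicate 1 and 46 in polysome replicate 2, and a 33-nt fragment shared by 23 tRNA-Asp genes had 5178 and 108 reads. No explanation was tested.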

How the results depend on the processing

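Counting both orientations as listed, leaving out low sequences, scaling lists without TMM, the denominator without miRNA reads, leaving out AT3G43832 and all reads of a MIR gene for single libraries were added after the data were seen. The 24-nt difference kept its sign under each alternative, from 2.37 to 13.9 percentage points, with 8.67 to 13.3 when a library was left out. With 2 libraries per fraction no share can pass the exact permutation test used, and depth limits the features with few reads. Of 531 values for named features, 489 kept their sign and side of the threshold and 25 passed the threshold, AT1G76550 and GCN2 in 6 settings each. A setting with too few reads for a feature gave no value for it. Where a cause is not named below, the cause was not tested.

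In a replicate block, paired by replicate number alone (2 pairs, correlation 0.294 of their differences), 5 features were called, all lower in polysomes, and the snoRNA and snRNA list of 20-22 nt did not pass (adjusted p = 0.118). The count of 0 features was 83 with DESeq2, 183 without the low-count filter, 5 at a mean of at least 10 CPM (fewer features tested), 3 with reads that match 1 place, 1 with each place counting the full read, and 91 to 403 with a library left out. The miRNA count of 0 was 2 without the low-count filter and 1 to 3 with a library left out; adjusted over the list alone it was 4 and 1 to 3. The count of 8 lists called was 0 with an estimated correlation and 6 to 9 with a library left out, where lists not among the 8 can be called.

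The 21-nt difference of 0.103 points was -0.155 for distinct sequences, -8.41 without structural and organelle RNA, -0.123 for genome-matched reads, -2.48 without miRNA reads as well, and -5.49 to 5.70 with a library left out. The 22-nt difference of -0.563 was 0.207 for distinct sequences and 0.143 without structural and organelle RNA. For the shares of classes, miRNA genes were at -4.77 with reads that match 1 place and -3.85 to 9.05 with a library left out, and TAS loci at 0.00369 with both orientations and -0.0360 to 0.0346 with a library left out. For the first base, A at 24 nt was at -0.736 for distinct sequences, U at 21 nt at -8.17 with reads that match 1 place, and for pseudogenes A at 24 nt was at -1.64 for distinct sequences and -2.08 without AT3G43832 and U at 21 nt at 0.0915 with reads that match 1 place.

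In the order distinct sequences, without structural and organelle RNA, reads that match 1 place and both orientations, the TRAP 21-nt share was 7.09%, 16.4%, 8.04% and 16.2% and its 24-nt share 46.6%, 57.6%, 64.7% and 37.5%. The seedling 21-nt share was 7.51%, 33.8%, 15.4% and 31% and its 24-nt share 46.6%, 36.7%, 44.1% and 27.3%.

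Signs of log2 fold changes turned without TMM for TAS1B (0.40), TAS2 (0.068) and TAS3A (0.51) at 20-22 nt, TAS3A at 23-25 nt (0.19), AT4G21370 (0.42), miR158a-3p (0.047) and miR166a-3p (0.12), and without the low-count filter for TAS1B (0.032), TAS3A (0.12) and AT4G21370 (0.039). AT4G21370 was at 0.43 with reads that match 1 place and miR171a-3p at -0.27 with all reads of the gene. With a library left out, TAS1B ranged from -0.40 to 0.070 and TAS3A from -0.33 to 0.054 at 20-22 nt, TAS3A from -0.97 to 0.49 and AT1G47880 from -0.078 to 1.12 at 23-25 nt.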

Other observations

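The tests below were chosen after the results they bear on were seen, and for all but the one on the most abundant 24-nt sequences the outcome, or that of a close variant, was known when the bounds were written down.

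Both polysome libraries had a higher 24-nt share than both monosome libraries. If the larger share of rRNA and organelle fragments in the monosome libraries caused this, the difference would shrink below the polysome SD without structural and organelle RNA, but it was 12.3 percentage points. Leaving out miRNA reads as well gave 13.9, so these explanations alone do not account for the pattern. Leaving out the 100 most abundant 24-nt sequences, which held 13.1% of the polysome 24-nt reads, gave 10.8. They held too few reads for their removal to bring the difference below the polysome SD, so this cannot decide on abundant sequences. Counted as distinct sequences the difference was 2.37 percentage points, below the polysome SD of 3.30 for reads, so a part played by abundant sequences stays open. A biological hypothesis, that 24-nt siRNAs may associate with polysomes, stays open and was not tested further. The depth of the libraries, 8490068 and 9461364 against 3381062 and 3118492 reads, and the share of 15-17 nt reads differed between the fractions in the same way, so that neither depth nor RNA breakdown is excluded.

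Some abundant sequences had only a few reads in 1 library, such as miR161.1 in polysome replicate 1. A true lack of small RNAs from those places would lower overlapping sequences too, but where 262 low sequences, which are the 270 found less 8 without an exact match to the genome, had a median log2 ratio of -6.70, the overlapping sequences of 251 of them had a median of -0.64. Counts lost when the lists were written are a candidate explanation, since 5.32% of the sequences listed in both orientations with at least 100 reads in polysome replicate 1, which should have equal counts, were more than 30-fold apart. In the TRAP library, with 77 low sequences, 0 of 319 pairs were apart, so the explanation has no such evidence there. No biological explanation was tested.

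The 61 loci that were nearly empty in the seedling library could reflect counts lost from single sequences of that list, in which 21.9% of pairs with at least 100 reads were apart. When 75 loci, 54 of the 61 among them, were picked as low from their sequences with 5 or more reads in an inflorescence library, such a loss would spare the remaining, rarer sequences, but the log2 ratio of seedling to inflorescence reads of these was lower by -5.20 (bootstrap interval over loci -5.84 to -4.67) than at loci not picked. Some of the picked loci adjoin or overlap, such as AT2G16575 and AT2G16580, so the interval treats related loci as independent and may be too narrow. For the other 7 loci this explanation stays open, as they had too few reads to be picked in this way and their value of -6.15 is limited by how they were chosen. A lower yield of 23-25 nt siRNAs in the seedling library as a whole would lower the other loci too, and their median log2 ratio was 0.10. Single sequences were often lower elsewhere too: 64.8% of the 21828 compared there were over 8 times lower in the seedling library. In the low loci this held for 99.6% of 2855. A difference between tissues may underlie the pattern, as a hypothesis found on these data and not tested. Tissue and the ribosome step differ together between these libraries, so which of them matters stays open.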
